A study of Homo sapiens with 42 samples.

How the data were processed

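Polyadenylated RNA of the human cell lines OCI-AML3 and NOMO1 was sequenced as unstranded paired-end libraries, 42 in all, in 14 groups of 3. Per the labels, reads were checked with FastQC 0.11.9 and MultiQC 1.14, and the tools listed are STAR 2.11a, featureCounts of Subread 2.0.6 and DESeq2 1.44.0 on build hg38. The authors deposited 1 table of raw read counts per gene, whose values are whole counts that have not been scaled. Because reads carry no strand, counts of genes that overlap on opposite strands may be shared. Reads were not analysed. Of the columns, 3 (OCIAML3_SEL_D6) that match no labelled library and repeat those of OCIAML3_SEL_D1 were not used, 1 gene with an empty cell was left out, and 19 genes have no symbol, leaving 58869. Gene positions are those of GENCODE 29 on GRCh38, matched by Ensembl identifier (58595 genes). The labels write the menin inhibitor's number in 2 ways, and the series description's form is used.

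Groups and doses (100 nM of each drug) were taken from the labels. Each line was fitted on its own with 7 group means over 21 libraries in edgeR 4.0.16 under R 4.3.3, with filterByExpr, TMM scaling, robust quasi-likelihood dispersions and Benjamini-Hochberg adjustment per comparison at 0.05. This left 16384 genes in OCI-AML3 and 16561 in NOMO1. The 8 comparisons per line were VTP-50469 and the combination at day 3 and day 6 against DMSO of the same day, selumetinib against DMSO day 3, the combination against VTP-50469 at each day, and the interaction at day 3. The 3 differences between the lines came from 1 fit of all libraries (18707 genes). Replicate numbers did not pair the libraries: after removing group means, correlations of libraries with the same number ran from -0.089 to 0.041 in OCI-AML3 and from -0.076 to 0.049 in NOMO1. Replicates were therefore not paired. These choices, the gene lists, the rules for naming genes and the alternatives were fixed before the data were examined, apart from the additions named in the closing section.

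Gene lists written beforehand (18 tested and 5 of markers of other cell types) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists and comparisons of a line, and again with the correlation estimated from the data. Members called are also given adjusted over the list alone. Overlaps between lines and days were tested by Fisher's exact test (1-sided). Genes named are, per comparison, the 5 of largest rise and 5 of largest fall with at least 5 CPM in 1 group and no overlap between replicates, up to 4 called members of smallest adjusted p per list described (which of these are printed was chosen after the values were seen), and 20 genes followed in every comparison. Symbols without a gene name were left out. Some genes these rules name are not reported here, so lists of the largest changes may hold fewer than 5. For interactions and line differences the condition on replicates was dropped. CPM use TMM-scaled totals of a line, or of both in line differences, but unscaled ones for markers of other cell types. A fold against a group with 0 counts is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact binomial interval of 95%.

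In simulated counts with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, edgeR found 80.6%, 88.1% and 100% in the OCI-AML3 VTP-50469 day 6 design (7.3% of calls false). In NOMO1 it found 67.2%, 97% and 100% (6.4% false). In the interaction design these shares were 35.8%, 76.1% and 98.5% in OCI-AML3 (8.5% false) and 38.8%, 89.6% and 97% in NOMO1 (6.8% false). A 1.5-fold interaction was mostly missed in this simulation of few changes. In the VTP-50469 line difference they were 44.8%, 82.1% and 97% (3.9% false).

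Alternatives were DESeq2 1.42.0, relative log expression size factors, library totals, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, only the compared groups in the fit, DMSO day 6 as the control, removal of mitochondrial genes, and leaving out each library in turn.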

Results

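RNA sequencing read counts were measured in OCI-AML3, an acute myeloid leukaemia line with mutant NPM1, and in NOMO1, a line of the same disease with a KMT2A rearrangement. Each line had 7 groups of 3 libraries, 42 in all: DMSO at day 3 and day 6, the menin inhibitor VTP-50469 (100 nM) at day 3 and day 6, the MEK inhibitor selumetinib (100 nM), and the combination at day 3 and day 6. Menin holds KMT2A at its target genes, and MEK is the kinase that activates ERK. Selumetinib alone is labelled as 1 day in 1 field and as day 3 in the titles of replicates 2 and 3, and the count table holds its 3 OCI-AML3 columns again under day 6 names (58870 of 58870 rows equal), so its time is uncertain; no DMSO group of 1 day is labelled, and the labels do not say how long selumetinib lasted in the combination. Total counts per library ran from 15561248 to 24262960 in OCI-AML3 and from 15264862 to 29168628 in NOMO1, and 16742 to 22759 genes had at least 1 count. The labels do not say if the 3 libraries of a group came from separate cultures. The spread behind p-values is pooled over all groups of a fit, which differ in scatter, and may be technical. Intervals and floors cover counting error only. In each line 1 DMSO group is the control of several comparisons, so these are not independent. Below, a gene loses its call, or moves (log2 fold change altered over 1.5 times), without a library when that library alone is left out, and adjusted p stands for the fold where a group then has at most 3 counts.

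Some libraries stood apart from their group or line. The plot of principal components puts NOMO1 DMSO day 3 away from day 6. In OCI-AML3, VTP-50469 day 3 replicate 2 lies off its partners, towards day 6. Selumetinib replicate 1, whose title lacks day 3, lies apart too (cause not tested). Between replicates the highest scatter (chi-square per gene over 20 reads, 1 if only counting error) was that of NOMO1 VTP-50469 day 3 replicate 1, at 73.85 and 79.57 against its partners and 5.69 between these; for OCI-AML3 replicate 2 it was 34.78 and 33.69, and 4.49 between its partners. Mitochondrial transcripts took 17.8 ± 0.2% of counts in NOMO1 DMSO day 3 (SD, n = 3), 3.2 ± 0.48% in DMSO day 6 and 3.4% to 6.3% in the treated NOMO1 groups. In OCI-AML3 this share was 2.5 ± 0.13% and 3.2 ± 0.66% in the DMSO groups, 4.0 ± 0.42% with selumetinib, and 6.2 ± 0.17% and 12.3 ± 2.26% in the combination at day 3 and day 6. Between the DMSO days themselves, edgeR called 0 genes in OCI-AML3 (174 at an unadjusted p under 0.05, 1 by DESeq2). In NOMO1 it called 8447 (8746 by DESeq2), and 30 of 31 mitochondrial genes were lower at day 6, with a median log2 fold change of -2.82. NOMO1 day 3 comparisons are therefore also given against DMSO day 6, naming genes that turned, moved, or lost or gained a call. For all but selumetinib and the interaction this was added after the libraries were seen.

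**Figure D1:**
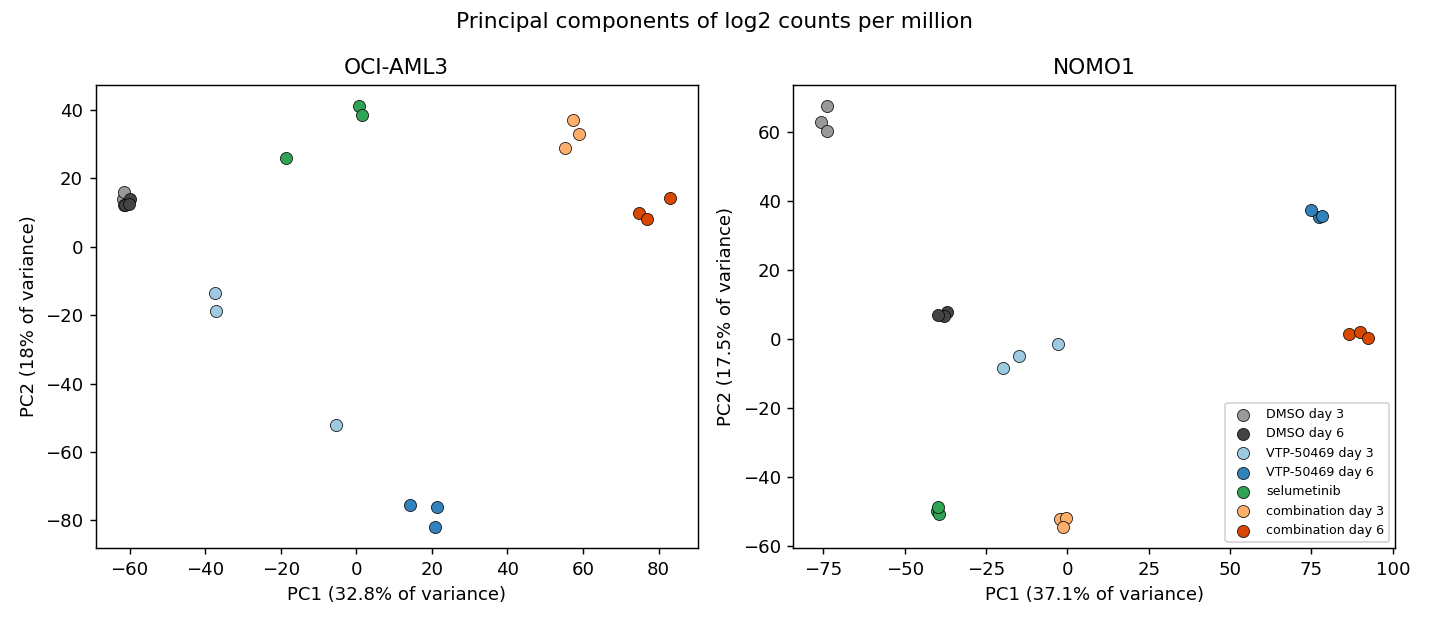
First and second principal component (percent of variance on the axes) of log2 CPM in OCI-AML3 (left) and NOMO1 (right), 1 point per library, coloured by group. In NOMO1 the 3 DMSO day 3 libraries lie at -75.8 to -74 on the first component and the 3 DMSO day 6 libraries at -39.7 to -36.9.

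Some markers of other cell types were detected, and whether they come from the lines' own cells was not tested. Of 12 erythroid markers only EPOR exceeded 5 CPM in any group, at 15.7 to 28.5, and of 8 megakaryocyte markers the highest reached 2.57 CPM in OCI-AML3 groups and 6.68 to 12.7 in NOMO1. Of 10 T and NK cell markers NKG7 was highest, at 1.68 to 5.15 CPM in OCI-AML3 and 108 to 179 in NOMO1. Of 8 B cell markers, CD79B lay at 12.7 to 27.7 CPM in NOMO1, and EBF1 in OCI-AML3 lay at 6.75 and 6.11 in DMSO at day 3 and day 6, 14.1 and 24.5 with VTP-50469 and 29.4 and 34.2 in the combination. Of 10 epithelial and stromal markers, the highest in OCI-AML3 DMSO day 6 was PDGFRB at 0.628 CPM, against COL1A2 at 55.5 with VTP-50469 at day 6 and 4.84 in the combination. In NOMO1 KRT8 lay at 87.7 and 135 CPM in DMSO, 157 and 24.5 with VTP-50469 and 285 with selumetinib, and COL1A1 in the combination at 241 and 105.

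VTP-50469 against DMSO in OCI-AML3 asks how blocking menin changes an NPM1-mutant line. At day 6, interferon-stimulated genes rose together. BST2, an antiviral membrane protein, changed by 1.5 ± 0.07 (log2 fold change ± SE, n = 3 per group, adjusted p = 2.28e-15, edgeR), MX2 by 1.78 ± 0.10 and RSAD2 by 3.85 ± 0.29, and 25 of 25 interferon-stimulated genes rose (25 up adjusted over the list alone, median 6.86, adjusted p = 3.62e-31); for each list the members tested, the count adjusted over the list alone where it differs, the median log2 fold change and the camera test are given, and a call held with an estimated correlation unless that second adjusted p stands beside it as estimated. The antigen-presenting molecule HLA-DRA went from 0.149 ± 0.139 to 7.56 ± 1.11 CPM (SD, n = 3), with its activator CIITA changed by 2.69 ± 0.41, and 8 of 10 MHC class II genes rose (median 4.16 or 3.43 with floor genes at their bound, adjusted p = 1.87e-05). Among menin targets the growth factor receptor gene FLT3 (-1.64), the survival gene BCL2 (-1.94) and the HOX partner PBX3 (-1.18) fell, the transcription factor gene MEF2C (1.48) and LMO2 (0.84) rose, and 5 of 18 menin-KMT2A targets outside the HOX clusters rose and 11 fell (median -0.41, adjusted p = 0.00153, or 0.0601 estimated). Of the homeobox genes HOXA13 (0.68), HOXB2 (0.96) and HOXA5 (1.10) rose, and 11 of 18 HOXA and HOXB genes rose and 1 fell (median 0.68, adjusted p = 0.0171, or 0.164 estimated).

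Nucleolar and stress-response genes were lower at day 6, with POLR1B (-0.68), RRP12 (-0.76) and NPM1 (-0.67) and the cystine transporter gene SLC7A11 (-1.68) among them. Here 16 of 24 MYC and nucleolar genes fell (17 down adjusted over the list alone, median -0.33, adjusted p = 5.03e-06, or 0.226 estimated), and 1 of 20 amino acid and protein stress genes rose and 15 fell (1 up and 16 down adjusted over the list alone, median -0.99, adjusted p = 6.09e-12, or 0.0662 estimated). Of ERK targets PHLDA1 (2.38), ETV5 (1.45), SPRY4 (0.68) and DUSP6 (1.25) rose and EGR1 fell. Of 9 MEK signature genes 5 rose (median 0.68, adjusted p = 0.0294, or 0.313 estimated). Of 16384 genes, edgeR called 3074 higher and 2615 lower. Largest by fitted fold were the rises of RGS4, LHFPL1, TLR3, KRT17 and GPA33 (at least 245, 196, 193, 168 and 162-fold). IFITM1 rose 874-fold by counts (interval 299 to 4240). Falls were led by PDPN (-6.08), S100P (-5.38), CNTN4 (-5.32), CLGN (-4.77) and EGR1 (-4.44). Of the genes followed throughout, CDK6 (0.48), ITGAM (2.90), LYZ (1.23) and MEN1 (0.22) rose and MEIS1 (-0.37) and MYC (-0.79) fell. Not passing were HOXA9, CD14, MCL1, NRAS and KMT2A (-0.20 to 0.26, adjusted p 0.122 to 0.965). CNTN4 (adjusted p = 0.000747) had a group at 0 counts without VTP-50469 replicate 2. PDPN (adjusted p = 4.02e-07) had a group at 0 counts without VTP-50469 replicate 3. KRT17 (adjusted p 0.061 to 0.0618) lost the call without any 1 DMSO replicate. MEN1 (0.19 to 0.20) lost the call without DMSO replicate 1 or 2, or VTP-50469 2 or 3. MEIS1 (-0.34 to -0.27) lost the call without DMSO replicate 1, or VTP-50469 1 or 2.

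At day 3 of VTP-50469 the interferon-stimulated genes had begun to rise in OCI-AML3. MX1 went from 0.621 ± 0.0769 to 5.88 ± 4.73 CPM (SD, n = 3), BST2 changed by 0.37 ± 0.07, and 21 of 25 interferon genes rose (24 up adjusted over the list alone, median 3.24, adjusted p = 2.66e-16, or 0.106 estimated). This rise was uneven between libraries, since without replicate 2 the list had 13 up, median 1.56, adjusted p = 3.77e-39. HLA-DRA and CIITA were already higher, by 3.27 ± 0.62 and 1.83 ± 0.42. FLT3 changed by -0.94 ± 0.12, PBX3 (-0.88) and BCL2 (-0.80) fell and HOXA13 (0.51) rose; 3 of 18 menin-KMT2A targets rose and 7 fell (3 up and 8 down adjusted over the list alone, median -0.18, adjusted p = 0.000261). The early response genes EGR3 (-2.41), PLAUR (-1.54) and IER2 (-0.64) fell, and 1 of 20 other ERK output genes rose and 6 fell (median -0.30, adjusted p = 9.39e-05).

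The test called 1064 genes higher and 724 lower, and 964 in all without VTP-50469 day 3 replicate 2. Largest were the rises of BBOX1 (7.09), SAMD11 (6.38), GJA1 (6.11), ABCA10 (6.02) and NPPC (5.83) and the falls of PDPN (-3.57), PTGIS (-3.14), COL8A2 (-2.60), DLX2 (-2.50) and EGR1 (-2.48). Of the genes followed throughout, MEF2C (0.78), ETV5 (0.77), PHLDA1 (1.48) and ITGAM (2.62) also rose and MYC (-0.32) fell. Not passing were MEIS1, HOXA9, CDK6, DUSP6, SPRY4, CD14, LYZ, MCL1, NRAS, MEN1 and KMT2A (-0.19 to 0.87, adjusted p 0.0739 to 0.978). Between day 3 and day 6, 969 genes were called higher at both times (200 expected if genes were independent) and 645 lower at both (116 expected). ABCA10 (3.80), MEF2C (0.50), PHLDA1 (0.85) and ITGAM (1.69) moved without VTP-50469 replicate 2. ETV5 (0.33 to 0.80) and MYC (-0.34 to -0.17) lost the call without any 1 DMSO replicate, or VTP-50469 replicate 2.

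In NOMO1 the same treatment asks what menin does in a KMT2A-rearranged line, and at day 6 the leukaemic homeobox programme fell while myeloid differentiation genes rose. MEIS1 (ENSG00000143995.20, chromosome 2, 66433452 to 66573869 in GRCh38), a HOXA9 partner that sustains leukaemia, dropped from 24.7 ± 2.46 to 0.226 ± 0.0543 CPM (SD, n = 3), a log2 fold change of -6.76 ± 0.23 (adjusted p = 1.23e-17, edgeR). PBX3 changed by -3.02 ± 0.12, HOXA9 by -2.82 ± 0.14 and FLT3 by -2.49 ± 0.14. CD14 (ENSG00000170458.14, chromosome 5, 140631728 to 140633701), the lipopolysaccharide co-receptor of monocytes, rose from 2.49 ± 0.233 to 263 ± 14.3 CPM, the macrophage growth factor receptor gene CSF1R by 4.24 ± 0.11 and the scavenger receptor gene CD36 by 5.85 ± 0.18. Here 22 of 25 monocyte and macrophage genes rose and 1 fell (median 1.88, adjusted p = 6.56e-30), and 18 of 20 neutrophil and granule genes rose (median 1.26, adjusted p = 5.84e-13), with MMP9 (3.25), S100A12 (1.84) and CAMP (1.86) as examples of the second. Of the HOX genes HOXA10 (-2.10) and HOXA3 (-4.75) fell, and 1 of 12 HOXA and HOXB genes rose and 6 fell (median -1.97, adjusted p = 0.000489). Of menin targets JMJD1C changed by -1.64 ± 0.07, and 9 of 20 menin-KMT2A targets rose and 10 fell (median -0.64, adjusted p = 0.000202, or 0.0651 estimated).

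Growth genes were lower at day 6. GNL3 (-1.46), NOLC1 (-1.18), MCM3 (-0.96) and MCM2 (-0.88) and the sterol enzyme gene LSS (-1.50) fell; 22 of 24 MYC and nucleolar genes fell (23 down adjusted over the list alone, median -0.81, adjusted p = 2.72e-12). Likewise 1 of 30 DNA replication and mitosis genes rose and 26 fell (1 up and 27 down adjusted over the list alone, median -0.67, adjusted p = 1.63e-08, or 0.189 estimated), and 19 of 21 cholesterol synthesis genes fell (median -1.10, adjusted p = 1.84e-15, or 0.0627 estimated). Most MEK signature genes rose, DUSP6 (2.34), DUSP4 (3.72) and CCND1 (1.00) among them. Of this list 7 of 9 rose and 1 fell (median 1.29, adjusted p = 0.00033, or 0.153 estimated). The cytokine genes CCL3 (3.61), CCL2 (4.81) and IL1B (3.97) rose, and 15 of 19 chemokine and cytokine genes rose and 1 fell (median 2.48, adjusted p = 0.000459, or 0.381 estimated). In contrast to OCI-AML3, HLA-DRA (-1.80), CD74 (-0.75) and CIITA (-1.51) fell, and 2 of 12 MHC class II genes rose and 6 fell (2 up and 7 down adjusted over the list alone, median -0.76, adjusted p = 0.0172, or 0.397 estimated). edgeR called 3930 genes higher and 4156 lower of 16561 tested. Largest were the rises of GFRA2 (at least 265-fold), DEFA1B (at least 225-fold), DEFA3 (9.41), CEACAM8 (7.57) and CD163 (7.51) and the falls of CLEC2A (at least 228-fold), HOXA7 (at least 129-fold), SOCS2 (-6.90), MEIS1 and CASC10 (-6.50). Reads of DEFA1B and DEFA3 may be shared because their sequences are near identical. Of the genes followed throughout, SPRY4 (1.29), ETV5 (1.24), PHLDA1 (2.81), LYZ (0.74), MCL1 (0.63) and KMT2A (0.89) also rose and MEF2C (-1.63), CDK6 (-1.33), MYC (-1.19), BCL2 (-1.68) and NRAS (-0.51) fell. Not passing were ITGAM and MEN1 (-0.17 to 0.21, adjusted p 0.152 to 0.181). KMT2A (0.56) moved without VTP-50469 replicate 1.

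**Figure D2:**
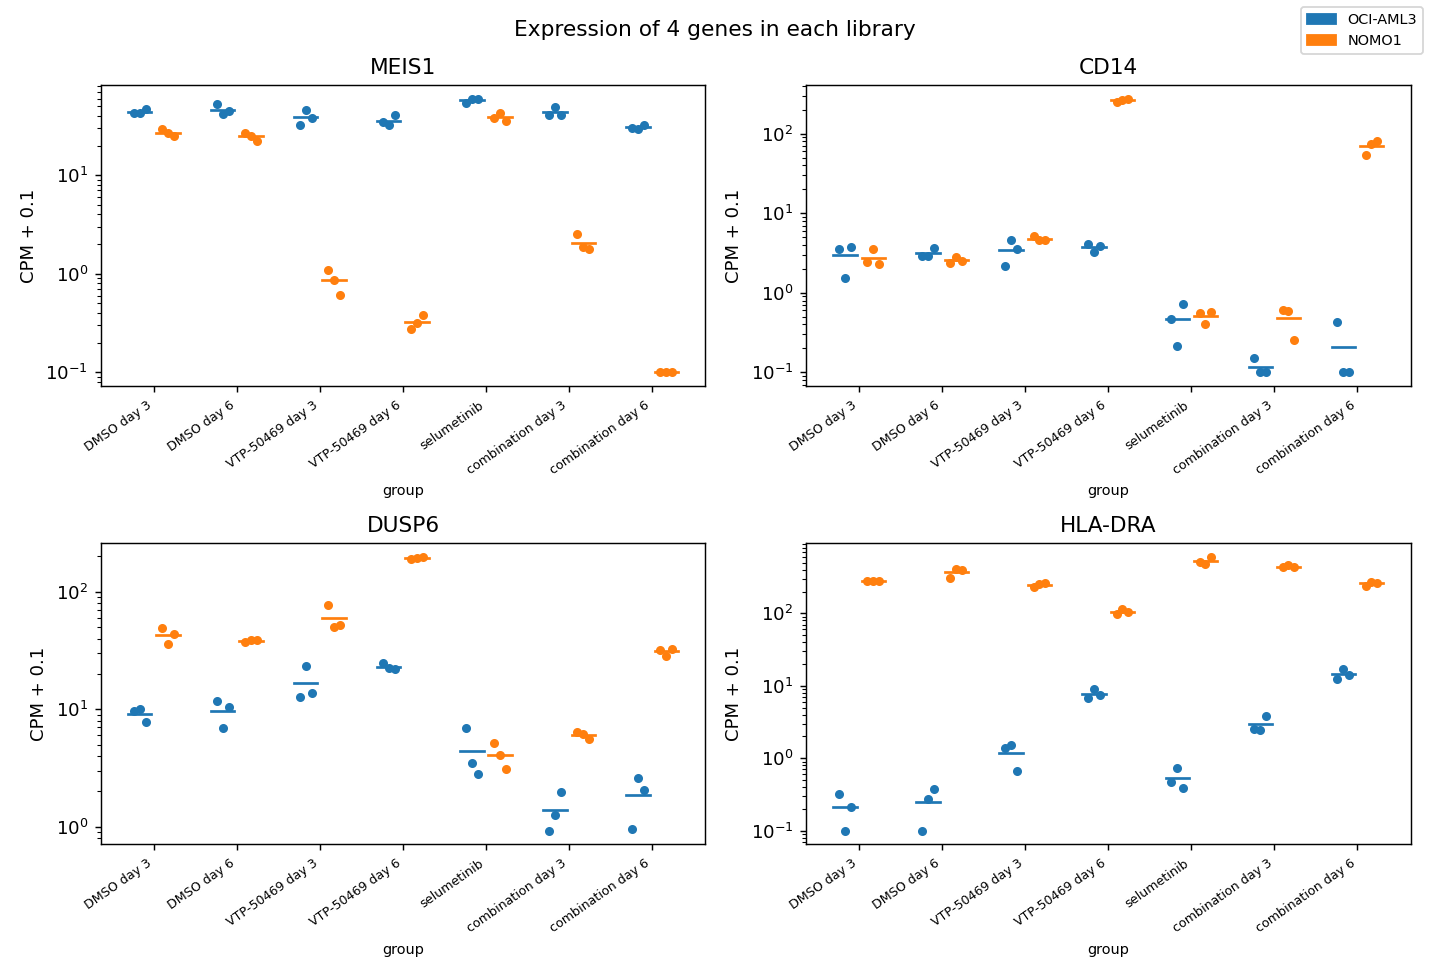
CPM (log10 axis, 0.1 added) of MEIS1, CD14, DUSP6 and HLA-DRA in each library of OCI-AML3 (blue) and NOMO1 (orange), with a bar at each group mean. In NOMO1 MEIS1 falls from 24.7 in DMSO day 6 to 0.226 with VTP-50469, while in OCI-AML3 it stays between 30.6 and 57.6 in all groups.

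At day 3 the NOMO1 homeobox genes had already fallen against DMSO day 3, whose libraries held 17.8% mitochondrial counts. MEIS1 changed by -5.16 ± 0.20 (n = 3 per group, adjusted p = 1.46e-16, edgeR), PBX3 by -2.60 ± 0.12, HOXA9 by -1.86 ± 0.13, and against DMSO day 6 by -5.03, -2.62 and -1.62. Here 7 of 12 HOXA and HOXB genes fell (8 down adjusted over the list alone, median -1.01, adjusted p = 0.006, or 0.0763 estimated); against DMSO day 6 the values were 1 up and 7 down, median -1.28, adjusted p = 0.000152. Monocyte genes TLR4 (2.68), MNDA (2.27) and FCN1 (0.99) and the granulocyte genes MMP9 (2.42), CSF3R (0.78) and CEBPE (1.18) rose. Here 12 of 20 neutrophil genes rose and 2 fell (median 0.87 or 0.81 with floor genes at their bound, adjusted p = 0.00112, or 0.0842 estimated); against DMSO day 6 they had 16 up, median 1.56, adjusted p = 1.34e-24.

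Some genes of replication and sterol synthesis changed sign with the control. MCM2 was at 2.17 against DMSO day 3 and -0.24 against day 6, TOP2A at 1.15 and -0.41, CYP51A1 at 3.34 and -0.53, and SQLE at 1.70 and -0.62. The 30 replication genes had 14 up and 6 down, median 0.17, adjusted p = 0.0722 against DMSO day 3 (0.000598 without VTP-50469 replicate 1) and 11 down, median -0.22, adjusted p = 0.00696 against day 6, and the 21 cholesterol genes 9 up and 5 down (9 and 6 adjusted over the list alone), median 0.14, adjusted p = 0.51 and 19 down, median -0.57, adjusted p = 3.27e-11. The test called 4922 genes higher and 3758 lower, and 2111 and 2388 against DMSO day 6. Largest were the rises of CYP4F3 (at least 119-fold), P2RY13 (6.63), PRG3 (6.37), ELN (6.27) and STRA6 (5.84) and the falls of DYNC1I1 (-5.50), DLX5 (-5.42), IGKJ1 (-5.24), MEIS1 and CLEC2A (-4.04). Followed genes DUSP6 (0.48), SPRY4 (1.57), CD14 (0.82), ITGAM (0.57), LYZ (0.59) and MCL1 (0.43) rose and MEF2C (-1.26) and CDK6 (-0.95) fell. Not passing were FLT3, ETV5, PHLDA1, MYC, BCL2, NRAS, MEN1 and KMT2A (-0.41 to 0.59, adjusted p 0.0577 to 0.923). At both days 1987 genes were called higher (1168 expected) and 1566 lower (943 expected), while 1013 were higher and then lower (1235 expected) and 542 the reverse (892 expected). Sharing DMSO day 6 as control, which adds overlap, the days gave 1410 (501 expected), 1484 (599), 123 (530) and 275 (567). Against DMSO day 6 FLT3 (-0.90), MYC (-0.22) and BCL2 (-0.87) turned and passed and ITGAM (-0.17) and MCL1 (-0.05) turned without passing. There SPRY4 (0.69) and LYZ (0.19) lost the call, NRAS (-0.34) gained it and FCN1 (1.5), CSF3R (0.51), CYP4F3 (4.78), PRG3 (2.69), STRA6 (3.73), MEF2C (-2.01) and CDK6 (-1.55) moved. ELN (adjusted p = 0.00309) had a group at 0 counts without DMSO replicate 1. DUSP6 (0.26) and ITGAM (0.31) moved without VTP-50469 replicate 1. ELN (3.42) moved without VTP-50469 replicate 2.

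The VTP-50469 effects at day 6 were compared as NOMO1 minus OCI-AML3. In line differences, higher or lower means effect, not level. MEIS1 had a lower effect in NOMO1, with a difference of -6.33 ± 0.27 (adjusted p = 9.46e-22, edgeR), as did PBX3 (-1.78), HOXA9 (-2.56) and HOXA10 (-2.52), and 6 of 20 HOXA and HOXB genes were lower (median -0.47, adjusted p = 0.0015, or 0.0616 estimated). Myeloid genes had a higher effect in NOMO1, CD14 (6.53), CD36 (5.90) and CYBB (3.95) among them, and 18 of 25 monocyte genes were higher and 3 lower (median 1.77, adjusted p = 6.39e-19). Effects on antigen presentation and interferon genes were lower in NOMO1: HLA-DRA (-7.30), CIITA (-4.14) and MX1 (-6.42). Here 8 of 13 MHC class II genes were lower (9 down adjusted over the list alone, median -4.14, adjusted p = 7.27e-10), and 22 of 25 interferon genes were lower (median -5.54, adjusted p = 8.83e-21). The sterol gene HMGCS1 (-3.0) was also lower in NOMO1 and stress genes CEBPB (3.67) and SLC7A11 (4.65) higher, and 21 of 21 cholesterol synthesis genes were lower (median -1.27, adjusted p = 1.87e-20). In all 3098 genes were called higher and 3144 lower of 18707. Largest differences upward were CLEC10A (10.62), S100B (0.992 to 96.7 and 0.0674 to 0 CPM), PLA2G7 (0.523 to 16.6 and 0.101 to 0 CPM), PPM1E (0 to 0.277 and 14.6 to 2.63 CPM) and C5AR1 (7.99), and downward LHFPL1 (0.267 to 0.139 and 0 to 9.41 CPM), CLEC2B (170.0 to 11.6 and 0 to 0.769 CPM), IFIT1 (-10.84), TLR3 (0.0925 to 0.0782 and 0 to 9.26 CPM) and EPCAM (5.97 to 0.82 and 0 to 1.31 CPM), with CPM given as DMSO to VTP-50469 in NOMO1 and then OCI-AML3 where a group held at most 3 counts. Of the genes followed throughout, DUSP6 (1.16), MCL1 (0.70) and KMT2A (0.80) differed upward and MEF2C (-3.04), FLT3 (-0.78), CDK6 (-1.74), ITGAM (-2.62), LYZ (-0.42), MYC (-0.33), NRAS (-0.48) and MEN1 (-0.32) downward. Not passing were SPRY4, ETV5, PHLDA1 and BCL2 (-0.14 to 0.68, adjusted p 0.122 to 0.773). Genes tested in both lines and called higher in both numbered 1034 (664 expected if genes were independent, Fisher p = 8.62e-70), and 964 were lower in both (675 expected, p = 5.09e-44). Lower in OCI-AML3 and higher in NOMO1 were 665 (595 expected, Fisher p = 0.000211), and the reverse 731 (752 expected, p = 0.848). KMT2A (0.49) lost the call without NOMO1 VTP-50469 replicate 1. S100B (adjusted p = 0.0824) and PLA2G7 (adjusted p = 0.248) lost the call without OCI-AML3 DMSO replicate 2. LYZ (-0.41 to -0.38) lost the call without NOMO1 DMSO replicate 2, NOMO1 VTP-50469 1 or 3, OCI-AML3 DMSO 1 or 3, or OCI-AML3 VTP-50469 1 or 3. MYC (-0.34 to -0.27) lost the call without NOMO1 DMSO replicate 1 or 3, NOMO1 VTP-50469 2 or 3, any 1 OCI-AML3 DMSO replicate, or OCI-AML3 VTP-50469 2. MEN1 (-0.33 to -0.27) lost the call without NOMO1 DMSO replicate 1 or 3, NOMO1 VTP-50469 1 or 3, OCI-AML3 DMSO 1 or 2, or OCI-AML3 VTP-50469 2 or 3.

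Selumetinib alone against DMSO day 3 asks what MEK activity drives in each line. In OCI-AML3 the direct readouts of ERK fell, with the feedback inhibitor gene SPRY4 changed by -1.56 ± 0.17 (± SE, n = 3 per group, adjusted p = 2.28e-07, edgeR), CCND1 by -2.05 ± 0.21 and the early response gene EGR3 by -6.67 ± 0.55. Here 1 of 9 MEK signature genes rose and 7 fell (median -1.08, adjusted p = 9.39e-05, or 0.0703 estimated), and 1 of 20 other ERK output genes rose and 16 fell (1 up and 17 down adjusted over the list alone, median -1.33, adjusted p = 1.75e-13). The replication genes MCM7 (-1.02), E2F1 (-1.48) and MCM3 (-0.84) fell, and 29 of 30 replication and mitosis genes fell (median -0.72, adjusted p = 3.55e-24). Myeloid differentiation genes rose, LYZ (1.91), CD36 (1.00), CSF1R (3.12) and CTSG (1.16) among them; 12 of 22 monocyte genes rose and 4 fell (13 up and 5 down adjusted over the list alone, median 0.68, adjusted p = 2.05e-07). The p53 targets MDM2 (0.74) and CCNG1 (0.59) rose, and 13 of 20 p53 target genes rose and 3 fell (median 0.52, adjusted p = 3.72e-05). The test called 1920 genes higher and 2562 lower. Largest were the rises of BBOX1 (5.81), OLFML3 (5.41), PLD4 (4.13), FGD2 (3.71) and GASK1B (3.48) and the falls of EGR3, EGR1 (-5.48), CLGN (-5.24), C5AR1 (-5.11) and GPR84 (-4.74). Of the genes followed throughout, MEIS1 (0.39), FLT3 (0.83), CDK6 (0.57) and ITGAM (2.04) also rose and HOXA9 (-0.51), DUSP6 (-1.07), ETV5 (-0.67), PHLDA1 (-1.08), CD14 (-2.90), MYC (-0.69) and MCL1 (-0.40) fell. Not passing were PBX3, MEF2C, BCL2, NRAS, MEN1 and KMT2A (-0.06 to 0.09, adjusted p 0.445 to 0.971). MEIS1 (0.37) lost the call without DMSO replicate 1. DUSP6 (-1.03 to -0.80) lost the call without DMSO replicate 1 or 2, or selumetinib 2 or 3. ETV5 (-0.70 to -0.54) lost the call without any 1 DMSO replicate, or selumetinib replicate 2 or 3. PHLDA1 (-1.10 to -0.94) lost the call without any 1 DMSO replicate, or selumetinib replicate 1 or 2.

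In NOMO1 the same pathway genes fell. CCND1 changed by -3.89 ± 0.12 (± SE, n = 3 per group, adjusted p = 1e-18, edgeR), ETV5 by -5.42 ± 0.21 and DUSP6 (ENSG00000139318.8, chromosome 12, 89347232 to 89353271), the phosphatase that switches ERK off, by -3.40 ± 0.17. Here 8 of 9 MEK signature genes fell (median -3.55, adjusted p = 1.47e-14), and against DMSO day 6 8 down, median -3.68, adjusted p = 1.26e-40. Other ERK outputs HMGA1 (-0.69) and IER2 (-1.69) fell, and 17 of 20 other ERK output genes fell (median -1.77, adjusted p = 1.03e-05, or 0.198 estimated). Replication genes split against DMSO day 3, since 7 of 30 replication and mitosis genes rose and 15 fell (median -0.34, adjusted p = 0.234), while against DMSO day 6 they had 29 down, median -0.66, adjusted p = 2.4e-17. Menin targets SATB1 (1.51) and ZEB2 (1.47) rose, and 17 of 20 menin-KMT2A targets rose and 2 fell (median 0.66, adjusted p = 9.74e-06); against DMSO day 6 they had 11 up and 2 down, median 0.38, adjusted p = 0.000847. Further, 15 of 20 RAS pathway components rose and 2 fell (15 up and 3 down adjusted over the list alone, median 0.36, adjusted p = 0.0253, or 0.302 estimated), but 3 up and 3 down, median 0.03, adjusted p = 0.938 against DMSO day 6. The test called 4787 genes higher and 4170 lower, and 2177 and 3151 against DMSO day 6. Rises were largest for PRG3 (6.27), GABRA3 (5.73), VIL1 (3.97), KCNH2 (3.95) and CPVL (3.73), and falls for OCSTAMP (-6.62), GPR84 (-5.90), EGR1 (-5.44), ETV5 and ETV4 (-5.06). Followed genes that also rose were MEIS1 (0.53), PBX3 (0.42), MEF2C (0.54), FLT3 (1.52), CDK6 (1.12), LYZ (0.93), BCL2 (0.41) and NRAS (0.32), and HOXA9 (-0.81), SPRY4 (-2.88), PHLDA1 (-1.84), CD14 (-2.63), MYC (-0.17) and KMT2A (-0.57) fell. Not passing were ITGAM, MCL1 and MEN1 (0.00 to 0.15, adjusted p 0.311 to 0.977). Against DMSO day 6 BCL2 (-0.56) and ITGAM (-0.60) turned and passed and MEF2C (-0.21) turned without passing. There NRAS (0.04) lost the call, MCL1 (-0.49) gained it and HMGA1 (-0.34), IER2 (-0.45), ZEB2 (0.59), PRG3 (2.59), VIL1 (1.87), KCNH2 (2.10), CPVL (2.05), FLT3 (0.36), CDK6 (0.53), LYZ (0.53) and MYC (-0.51) moved. Scaled by library totals, MYC turned to 0.21. GABRA3 (adjusted p = 5.6e-06) had a group at 0 counts without DMSO replicate 1. MEF2C (0.47 to 0.58) lost the call without DMSO replicate 1 or 3, or any 1 selumetinib replicate. MYC (-0.16 to -0.12) lost the call without any 1 DMSO replicate, or selumetinib replicate 1 or 2. KMT2A (-0.48) lost the call without DMSO replicate 3, or selumetinib 2.

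The lines also differed in the selumetinib response. DUSP4 differed by -3.81 ± 0.43 (NOMO1 minus OCI-AML3, adjusted p = 1.63e-09, edgeR), ETV5 by -4.70 ± 0.34 and CCND1 by -1.79 ± 0.26, the last 2 falling in both lines and further in NOMO1. Here 1 of 9 MEK signature genes were higher and 6 lower (median -1.92, adjusted p = 3.58e-05, or 0.0525 estimated), and with DMSO day 6 as the control of both lines 1 up and 6 down, median -2.25, adjusted p = 5.98e-16. Of neutrophil genes S100A8 (-3.56) was lower in NOMO1, and 1 of 20 neutrophil genes were higher and 7 lower (1 up and 8 down adjusted over the list alone, median -0.60, adjusted p = 0.0015); with DMSO day 6 this list had 1 up and 3 down, median -0.34, adjusted p = 0.527. The test called 3755 genes higher and 2546 lower, against 870 and 927 with DMSO day 6. Upward the largest differences were PRRG1 (0 to 0.777 and 23.9 to 21.6 CPM), ALDH7A1 (0 to 1.22 and 8.24 to 13.2 CPM), RASL10B (0 to 0.331 and 12.4 to 8.5 CPM), KRT86 (5.26 to 3.51 and 0.706 to 0 CPM) and GIMAP6 (1.4 to 6.68 and 0.097 to 0 CPM), and downward APP (364 to 539 and 0 to 1.9 CPM), GNG11 (0.406 to 0 and 4.98 to 12.7 CPM), EPCAM (6.59 to 3.92 and 0 to 0.599 CPM) and GHR (0.372 to 0 and 5.32 to 7.87 CPM), in CPM as DMSO to selumetinib in NOMO1 and then OCI-AML3. Among the genes followed, PBX3 (0.53), FLT3 (0.74), CDK6 (0.61), MYC (0.57), BCL2 (0.52), MCL1 (0.45) and NRAS (0.28) differed upward and DUSP6 (-2.26), SPRY4 (-1.26), ITGAM (-1.84) and LYZ (-0.92) downward. Not passing were MEIS1, HOXA9, MEF2C, PHLDA1, CD14, MEN1 and KMT2A (-0.72 to 0.57, adjusted p 0.0841 to 0.847). In both lines 953 genes rose (546 expected) and 1131 fell (671 expected), not tested with DMSO day 6. With DMSO day 6 ALDH7A1 (-0.18), FLT3 (-0.43), BCL2 (-0.48) and MCL1 (-0.09) turned without passing. There PRRG1 (0.43), RASL10B (1.16), GIMAP6 (adjusted p = 0.503), GNG11 (adjusted p = 0.182), GHR (adjusted p = 1), PBX3 (0.35), CDK6 (0.03), MYC (0.14) and NRAS (0.01) lost the call and S100A8 (-1.22) and SPRY4 (-2.31) moved. GIMAP6 (adjusted p = 1) lost the call without OCI-AML3 DMSO replicate 3. GHR (adjusted p 0.0559 to 1) lost the call without NOMO1 DMSO replicate 1, any 1 NOMO1 selumetinib replicate, any 1 OCI-AML3 DMSO replicate, or OCI-AML3 selumetinib 2 or 3. PBX3 (0.45 to 0.54) lost the call without NOMO1 selumetinib replicate 1 or 2, OCI-AML3 DMSO 1 or 2, or OCI-AML3 selumetinib 1 or 3. NRAS (0.21 to 0.30) lost the call without NOMO1 DMSO replicate 2 or 3, NOMO1 selumetinib 2 or 3, OCI-AML3 DMSO 1 or 3, or OCI-AML3 selumetinib 1 or 3. SPRY4 (-1.20 to -1.02) lost the call without NOMO1 DMSO replicate 3, NOMO1 selumetinib 3, or OCI-AML3 selumetinib 1.

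Adding selumetinib to VTP-50469 was tested against VTP-50469 alone at the same day. In OCI-AML3 at day 6 the lysozyme gene LYZ changed by 2.08 ± 0.11 (± SE, n = 3 per group, adjusted p = 4.04e-13, edgeR), CD36 by 1.48 ± 0.09 and the calprotectin gene S100A9 by 2.34 ± 0.13. Here 14 of 22 monocyte genes rose and 1 fell (median 0.74, adjusted p = 6.01e-11), and 10 of 16 neutrophil genes rose and 1 fell (median 1.01, adjusted p = 1.25e-07). The menin target FLT3 (ENSG00000122025.14, chromosome 13, 28003274 to 28100592) changed by 1.97 ± 0.12, RUNX2 (0.98), ZEB2 (0.93) and RUNX1 (0.86) rose too, and 9 of 18 menin-KMT2A targets rose and 1 fell (median 0.27, adjusted p = 8e-05). Replication genes MCM3 (-1.42) and MCM7 (-1.61) fell, and 29 of 30 replication and mitosis genes fell (median -0.89, adjusted p = 2.55e-22). Interferon genes MX2 (-1.04) and BST2 (-0.52) were below VTP-50469 alone, and 21 of 25 interferon genes fell (22 down adjusted over the list alone, median -1.62, adjusted p = 0.000193, or 0.452 estimated). The test called 2737 genes higher and 4030 lower. Gains were largest for SNORD3A (4.26), CSF1R (3.85), CNR2 (3.79), S100A8 (3.61) and SLC24A4 (3.54) and losses for NPPC (at least 403-fold), KRT17 (at least 149-fold), KRT81 (at least 152-fold), ONECUT3 (at least 83.4-fold) and RGS4 (326-fold by counts, interval 89.9 to 2700.0). Among the followed genes PBX3 (0.68) and ITGAM (1.37) also rose and MEF2C (-0.37), DUSP6 (-3.68), SPRY4 (-2.05), ETV5 (-2.34), PHLDA1 (-1.39), CD14 (-5.00), MYC (-0.47) and MEN1 (-0.37) fell. Not passing were MEIS1, HOXA9, CDK6, BCL2, MCL1, NRAS and KMT2A (-0.25 to 0.23, adjusted p 0.0518 to 0.906). The combination libraries held 12.3% mitochondrial counts against 4.4% with VTP-50469 alone. CD14 (adjusted p = 3.55e-07) had a group at 0 counts without combination replicate 1. KRT17 (adjusted p 0.0549 to 0.0561) lost the call without any 1 combination replicate. MEF2C (-0.38 to -0.35) lost the call without combination replicate 2 or 3, or VTP-50469 1 or 3.

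At day 3 the added selumetinib lowered MEK signature genes in OCI-AML3. SPRY4 changed by -2.87 ± 0.18 (± SE, n = 3 per group, adjusted p = 1.58e-11, edgeR) and CCND1 by -3.81 ± 0.24, and 8 of 9 MEK signature genes fell (median -2.27, adjusted p = 5.77e-10). Myeloid genes VCAN (2.65), LYZ (2.08), CTSS (1.21) and CD36 (1.15) rose, and 11 of 22 monocyte genes rose and 4 fell (13 up and 4 down adjusted over the list alone, median 0.68, adjusted p = 8.47e-07). Replication genes MCM3 (-1.90) and MCM7 (-1.96) fell, and 26 of 30 replication and mitosis genes fell (median -1.33, adjusted p = 1.16e-24). Interferon genes did not pass as a list, since 2 of 25 interferon genes rose and 10 fell (median -0.74, adjusted p = 0.946), but without VTP-50469 day 3 replicate 2 they had 11 up and 3 down, median 0.52, adjusted p = 0.00237. The test called 2980 genes higher and 3927 lower. The 5 largest rises were CNR2 (4.66), FAM13A (4.11), HIST1H4H (3.85), CSF1R (3.84) and HIST1H2BD (3.81), and the 5 largest falls SPTB (at least 259-fold), SCN4A (at least 151-fold), NPPC (614-fold by counts, interval 110.0 to 24300.0), MMP1 (159-fold by counts, interval 43.6 to 1320.0) and CTXN1 (100.0-fold by counts, interval 33.9 to 488). Reads of the HIST1 genes may be shared between near-identical copies. Followed genes that rose were FLT3 (2.00), CDK6 (0.37), ITGAM (1.89) and NRAS (0.21), and those that fell HOXA9 (-0.40), DUSP6 (-3.67), ETV5 (-2.27), PHLDA1 (-1.02), CD14 (195-fold by counts, interval 34.7 to 7750.0), MYC (-1.79), BCL2 (-0.86) and MEN1 (-0.30). Not passing were MEIS1, PBX3, MEF2C, MCL1 and KMT2A (-0.16 to 0.32, adjusted p 0.123 to 0.423). PHLDA1 (-0.40) moved without VTP-50469 replicate 2. CDK6 (0.24 to 0.62) lost the call or moved over 1.5 times without combination replicate 2, or any 1 VTP-50469 replicate. NRAS (0.13 to 0.20) lost the call without combination replicate 2 or 3, or VTP-50469 1 or 2.

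Against DMSO, the combination at day 6 in OCI-AML3 raised most myeloid genes. LYZ changed by 3.31 ± 0.12 (± SE, n = 3 per group, adjusted p = 9.38e-17, edgeR), the endotoxin receptor gene TLR4 by 2.37 ± 0.11, S100A9 by 3.0 ± 0.13 and S100A8 by 4.48 ± 0.27. Here 15 of 22 monocyte genes rose and 5 fell (median 1.41, adjusted p = 8.59e-08), and 8 of 16 neutrophil genes rose and 1 fell (median 0.79, adjusted p = 0.000269). CD74, the class II chaperone, changed by 1.30 ± 0.09 and HLA-DRA went from 0.149 ± 0.139 to 14.4 ± 2.5 CPM (SD, n = 3), and 8 of 10 MHC class II genes rose (9 up adjusted over the list alone, median 4.35 or 3.46 with floor genes at their bound, adjusted p = 0.000191). The serine enzyme gene SHMT2 (-2.21) and SLC7A11 (-3.23) fell, and 18 of 20 stress genes fell (median -1.98, adjusted p = 4.54e-24). Progenitor genes gave 2 of 8 stem and progenitor genes rose and 1 fell (median -0.07, mean -0.20, set test upward, adjusted p = 0.662). The test called 3780 genes higher and 4343 lower, in libraries with 12.3% mitochondrial counts against 3.2% in DMSO. Rises were led by CNR2 (at least 214-fold), LHFPL1 (at least 98.7-fold), GPA33 (at least 95-fold), SNORD3A (9.33) and SIGLEC1 (8.73), and falls by SPTB (at least 117-fold), PTGIS (587-fold by counts, interval 105 to 23200.0), UBL4B (-7.63), STC2 (-7.53) and S100P (-7.05). From the followed set MEF2C (1.11), FLT3 (0.33), CDK6 (0.34), PHLDA1 (0.99) and ITGAM (4.27) also rose and MEIS1 (-0.60), PBX3 (-0.50), DUSP6 (-2.44), SPRY4 (-1.37), ETV5 (-0.89), CD14 (-4.74), MYC (-1.26) and BCL2 (-1.84) fell. Not passing were HOXA9, MCL1, NRAS, MEN1 and KMT2A (-0.15 to 0.04, adjusted p 0.0893 to 0.912). PBX3 (-0.38) lost the call and UBL4B (adjusted p = 1.88e-09) and CD14 (adjusted p = 3.68e-07) had a group at 0 counts without combination replicate 1. S100P (adjusted p = 0.000644) had a group at 0 counts without combination replicate 3. FLT3 (0.26 to 0.31) lost the call without combination replicate 2 or 3, or DMSO 1 or 3. CDK6 (0.29 to 0.35) lost the call without any 1 combination replicate, or any 1 DMSO replicate. PHLDA1 (0.86 to 0.87) lost the call without combination replicate 2, or DMSO 1.

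After 3 days of the combination, nucleolar and ERK output genes were below DMSO in OCI-AML3. RRP12 changed by -2.02 ± 0.10 (± SE, n = 3 per group, adjusted p = 8.39e-16, edgeR), the pyrimidine enzyme gene CAD by -1.85 ± 0.10 and HMGA1 by -1.42 ± 0.08; 23 of 24 MYC and nucleolar genes fell (median -1.31, adjusted p = 2.82e-28), and 17 of 20 other ERK output genes fell (median -1.84, adjusted p = 5.93e-10). Myeloid genes TLR4 (2.28), CTSS (1.5) and CD36 (1.36) rose, and 13 of 22 monocyte genes rose and 5 fell (median 0.91, adjusted p = 0.000193). Of the cell death genes BMF (3.70) rose, and 3 of 14 BCL2 family genes rose and 6 fell (median -0.08, adjusted p = 0.762). The test called 3652 genes higher and 4224 lower. Top rises were SPTLC3 (at least 255-fold), CNR2 (258-fold by counts, interval 71.1 to 2140.0), LHFPL1 (126-fold by counts, interval 42.6 to 611) and SAMD11 (5.98), and top falls SPTB (at least 164-fold), SCN4A (at least 150.0-fold), SLC12A8 (417-fold by counts, interval 74.5 to 16500.0), GPR84 (-7.80) and S100P (-7.67). Of the set followed, MEF2C (0.62), FLT3 (1.06), CDK6 (0.43), ITGAM (4.50) and LYZ (1.94) also rose and PBX3 (-0.56), HOXA9 (-0.39), DUSP6 (-2.79), SPRY4 (-2.92), ETV5 (-1.50), CD14 (165-fold by counts, interval 29.2 to 6570.0), MYC (-2.10), BCL2 (-1.66), MCL1 (-0.19) and MEN1 (-0.31) fell. Not passing were MEIS1, PHLDA1, NRAS and KMT2A (-0.01 to 0.46, adjusted p 0.225 to 0.934).

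The interaction asks if the combination at day 3 differs from the sum of the 2 single effects, each against DMSO day 3. Since selumetinib alone is labelled as 1 day in 1 field and the combination as 3, it may also hold a difference in time. In OCI-AML3 DUSP4 was -1.34 ± 0.14 from the sum (adjusted p = 3.96e-07, edgeR), DUSP6 -2.60 ± 0.49 and SPRY4 -1.30 ± 0.24, and 7 of 9 MEK signature genes were lower (median -1.34, adjusted p = 6.77e-11). Below the sum were also NOP56 (-0.78), POLR1A (-0.80), MCM3 (-1.06) and DHCR7 (-1.02), and 18 of 24 MYC and nucleolar genes were lower (22 down adjusted over the list alone, median -0.61, adjusted p = 1.53e-22). The test called 437 genes above the sum and 1028 below, and 970 in all without selumetinib replicate 1; chance was not excluded, as given below. Farthest above were CDR2L (3.50), KIF13A (2.95), DSEL (2.73), FLRT2 (2.45) and S100A8 (2.40), and farthest below SPARC (-10.48), BBOX1 (-9.82), MMP1 (0.556, 1.96, 5.43 and 0.0345 CPM), SCN4A (7.68, 0.957, 7.77 and 0 CPM) and IL7R (-5.58), where CPM are those of DMSO, selumetinib, VTP-50469 and the combination. Among genes followed, FLT3 (1.17) and MCL1 (0.34) lay above and ETV5 (-1.60), CD14 (2.88, 0.367, 3.33 and 0.0172 CPM), MYC (-1.10) and BCL2 (-0.80) below. Not passing were MEIS1, PBX3, HOXA9, MEF2C, CDK6, PHLDA1, ITGAM, LYZ, NRAS, MEN1 and KMT2A (-0.27 to 0.38, adjusted p 0.105 to 0.973). With DMSO day 6 as control KIF13A turned to -0.64. KIF13A (2.56 to 3.06) lost the call without combination replicate 2, any 1 DMSO replicate, selumetinib 1 or 2, or VTP-50469 3. IL7R (-6.12 to -3.38) lost the call or moved over 1.5 times without any 1 combination replicate, any 1 DMSO replicate, any 1 selumetinib replicate, or VTP-50469 replicate 2. CD14 (adjusted p 0.0703 to 0.095) lost the call without combination replicate 2 or 3, or selumetinib 3.

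In NOMO1 at day 6, selumetinib added to VTP-50469 again lowered ERK targets. CCND1 changed by -2.78 ± 0.10 (± SE, n = 3 per group, adjusted p = 1.53e-16, edgeR), ETV5 by -3.64 ± 0.16 and DUSP6 by -2.64 ± 0.14, and 8 of 9 MEK signature genes fell (9 down adjusted over the list alone, median -2.78, adjusted p = 1.08e-39). Nucleolar genes BOP1 (-1.51) and POLR1B (-1.31) fell, and 22 of 24 MYC and nucleolar genes fell (median -1.17, adjusted p = 3.02e-36). Class II genes HLA-DRA (1.29), CD74 (0.73) and HLA-DPA1 (1.66) rose, and 8 of 12 MHC class II genes rose (9 up adjusted over the list alone, median 1.38, adjusted p = 5.01e-14). The cytokine genes CCL3 (-2.81), CCL2 (-3.81) and IL1B (-3.43) fell, and 12 of 19 chemokine and cytokine genes fell (2 up and 12 down adjusted over the list alone, median -1.75, adjusted p = 1.21e-05, or 0.261 estimated). The test called 2057 genes higher and 2516 lower. Top gains were CCL24 (3.15), THBS1 (2.69), HP (2.64), HIST1H2BD (2.32) and HIST1H2AC (2.17), and top losses ETV4 (-6.23), MYEOV (-6.08), GPR84 (-5.89), ATP9A (-5.80) and ADGRG1 (-5.70). As for followed genes, PBX3 (0.70), HOXA9 (0.44), FLT3 (1.52), CDK6 (0.54), LYZ (0.72) and KMT2A (0.45) also rose and MEIS1 (at least 5.07-fold), MEF2C (-1.67), SPRY4 (-4.95), PHLDA1 (-1.20), CD14 (-1.92), MYC (-1.48), BCL2 (-0.57) and MCL1 (-0.29) fell. Not passing were ITGAM, NRAS and MEN1 (-0.21 to 0.13, adjusted p 0.18 to 0.256). HOXA9 (0.23 to 0.31) lost the call without combination replicate 2, or VTP-50469 2. KMT2A (0.28 to 0.75) lost the call or moved over 1.5 times without combination replicate 1 or 2, or any 1 VTP-50469 replicate.

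At day 3 in NOMO1 the same test used DMSO only in the shared fit. DUSP6 changed by -3.33 ± 0.16 (± SE, n = 3 per group, adjusted p = 6.2e-13, edgeR), MYC (ENSG00000136997.18, chromosome 8, 127735434 to 127741434) by -0.83 ± 0.07 and BOP1 by -1.36 ± 0.09. Here 9 of 9 MEK signature genes fell (median -4.14, adjusted p = 3.59e-37), and 23 of 24 MYC and nucleolar genes fell (median -0.96, adjusted p = 9.62e-29). The menin targets ZEB2 (1.28), CDK6 (1.15), SATB1 (0.70) and FLT3 (1.09) rose, and 12 of 20 menin-KMT2A targets rose and 3 fell (14 up and 3 down adjusted over the list alone, median 0.46, adjusted p = 3.54e-06). The test called 2637 genes higher and 3186 lower. The rises were largest in TXNIP (3.23), CYP27A1 (2.97), ADAMDEC1 (2.69), PDK4 (2.68) and ARRDC4 (2.55), and the falls in PLCH1 (-6.14), ETV4 (-5.96), KRT7 (-5.92), GPR84 (-5.87) and OCSTAMP (-5.85). Followed genes MEIS1 (1.38), PBX3 (0.94), LYZ (1.45) and NRAS (0.22) also rose and MEF2C (-1.18), SPRY4 (-5.20), ETV5 (-4.91), PHLDA1 (-1.74), CD14 (-3.58), BCL2 (-0.45) and MCL1 (-0.33) fell. Not passing were HOXA9, ITGAM, MEN1 and KMT2A (-0.07 to 0.41, adjusted p 0.0694 to 0.797). MEF2C (-0.77), PHLDA1 (-1.04) and MCL1 (-0.21) moved without VTP-50469 replicate 1. KRT7 (-2.08) lost the call without VTP-50469 replicate 2. NRAS (0.17 to 0.20) lost the call without combination replicate 2 or 3, or VTP-50469 1 or 3.

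Against DMSO, the combination at day 6 in NOMO1 lowered HOXA9, PBX3 and nucleolar genes. HOXA9 changed by -2.38 ± 0.14 (± SE, n = 3 per group, adjusted p = 2.72e-14, edgeR), PBX3 by -2.32 ± 0.12 and BOP1 by -2.53 ± 0.10, while MEIS1 (at least 564-fold) was left without a count. CSF1R rose by 4.84 ± 0.12, TLR4 by 3.39 ± 0.10 and the granulocyte receptor gene CSF3R by 1.02 ± 0.06; 20 of 25 monocyte genes rose and 1 fell (median 1.88, adjusted p = 4.36e-20), and 16 of 20 neutrophil genes rose and 2 fell (17 up and 2 down adjusted over the list alone, median 1.35, adjusted p = 5.33e-06). Biosynthetic genes GNL3 (-2.62), NOLC1 (-2.31) and LSS (-1.81) fell, and 23 of 24 MYC and nucleolar genes fell (median -1.90, adjusted p = 1.23e-31). Of the menin complex KMT2B (0.84) and WDR5 (-1.30) changed, and 8 of 16 menin and KMT2A complex genes rose and 6 fell (8 up and 7 down adjusted over the list alone, median 0.08, adjusted p = 0.922). The test called 4513 genes higher and 4662 lower. The strongest rises were GFRA2 (at least 548-fold), DEFA1B (at least 257-fold), DEFA3 (10.05), CLEC4E (at least 149-fold) and PDK4 (8.66), and the strongest falls MEIS1, OCSTAMP (-7.76), VAT1L (210.0-fold by counts, interval 71.7 to 1020.0), ETV4 (-7.09) and GJB6 (144-fold by counts, interval 49.1 to 702). Among followed genes PHLDA1 (1.61), CD14 (4.8), LYZ (1.46), MCL1 (0.34) and KMT2A (1.34) also rose and MEF2C (-3.30), FLT3 (-0.96), CDK6 (-0.79), SPRY4 (-3.66), ETV5 (-2.40), MYC (-2.67), BCL2 (-2.25), NRAS (-0.38) and MEN1 (-0.36) fell. Not passing were DUSP6 and ITGAM (-0.30 to 0.00, adjusted p 0.0755 to 0.991).

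By day 3 the combination had lowered ERK targets in NOMO1 against DMSO day 3. CCND1 changed by -2.52 ± 0.11 (± SE, n = 3 per group, adjusted p = 8.28e-17, edgeR), ETV5 by -5.00 ± 0.20 and DUSP6 by -2.85 ± 0.16; 1 of 9 MEK signature genes rose and 8 fell (median -3.63, adjusted p = 2.39e-09). Nucleolar genes BOP1 (-1.71) and GNL3 (-1.56) fell, and 21 of 24 MYC and nucleolar genes fell (median -0.77, adjusted p = 3.46e-10, or 0.0726 estimated); against DMSO day 6 they had 23 down, median -0.97, adjusted p = 6.34e-19. Monocyte genes TLR4 (3.39), CSF1R (3.60) and MNDA (2.44) rose, and 14 of 25 monocyte genes rose and 4 fell (median 0.68, adjusted p = 0.000129, or 0.183 estimated); against DMSO day 6 they had 12 up and 4 down, median 0.71, adjusted p = 1.48e-06. The 30 replication genes had 6 up and 16 down, median -0.38, adjusted p = 0.18 against DMSO day 3 and 28 down, median -0.72, adjusted p = 2.12e-11 against day 6. The test called 5158 genes higher and 4561 lower. Rising most were P2RY13 (7.47), PRG3 (7.46), ALOX15 (5.77), ITM2A (4.99) and MS4A3 (4.45), and falling most OCSTAMP (-8.15), EGR1 (-5.92), ETV4 (-5.50), RXFP1 (-5.39) and DYNC1I1 (-5.20). Of those followed, FLT3 (1.36), ITGAM (0.62) and LYZ (2.04) also rose and MEIS1 (-3.78), PBX3 (-1.66), HOXA9 (-1.63), MEF2C (-2.44), SPRY4 (-3.63), PHLDA1 (-1.15), CD14 (-2.77), MYC (-0.71) and BCL2 (-0.34) fell. Not passing were CDK6, MCL1, NRAS, MEN1 and KMT2A (-0.08 to 0.19, adjusted p 0.077 to 0.971). Against DMSO day 6 CDK6 (-0.40) and MCL1 (-0.38) turned and passed and ITGAM (-0.12) turned without passing. There FLT3 (0.20) lost the call and PRG3 (3.78), ALOX15 (2.78), ITM2A (2.15) and BCL2 (-1.31) moved. PHLDA1 (-0.96) lost the call without DMSO replicate 1.

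The interaction in NOMO1 uses DMSO day 3 as the control of both single drugs. The nucleolar gene WDR43 and the polyamine enzyme gene ODC1 were -1.54 ± 0.13 and -0.93 ± 0.10 from the sum (adjusted p = 8.27e-10 and 2.38e-08, edgeR), and 2 of 24 MYC and nucleolar genes were higher and 13 lower (2 up and 15 down adjusted over the list alone, median -0.42, adjusted p = 0.00112, or 0.34 estimated); with DMSO day 6 the list had 17 down, median -0.45, adjusted p = 5.1e-10. Replication genes changed sign, since 6 of 30 replication and mitosis genes were higher and 12 lower (6 up and 13 down adjusted over the list alone, median -0.29, adjusted p = 0.0184, or 0.591 estimated) while with DMSO day 6 they had 3 up, median 0.17, adjusted p = 0.0457. The test called 2541 genes above the sum and 3593 below, against 1310 and 988 with DMSO day 6, where 1390 were called both ways and 341 of these reversed. Farthest above were IGKJ1 (3.71), MT-TL1 (3.58), MTRNR2L12 (3.40), MT-TV (3.27) and SLC15A2 (3.23), and below ELN (-7.26), CYP4F3 (0, 0.0545, 5.92 and 1.15 CPM), STRA6 (-5.42), GABRA3 (-5.28) and PRG3 (-5.18), in CPM of DMSO, selumetinib, VTP-50469 and the combination where near the floor, and MT-TL1 and MT-TV are mitochondrial genes. The followed genes MEIS1 (0.85), PBX3 (0.52), HOXA9 (1.04), LYZ (0.52) and KMT2A (0.98) lay above and MEF2C (-1.71), SPRY4 (-2.33), MYC (-0.67), BCL2 (-0.86) and MCL1 (-0.32) below. Not passing were FLT3, CDK6, DUSP6, ETV5, PHLDA1, CD14, ITGAM, NRAS and MEN1 (-0.96 to 0.52, adjusted p 0.0646 to 0.92). With DMSO day 6 FLT3 (0.73) and ITGAM (0.65) turned and passed and BCL2 (0.11) and MCL1 (0.16) turned without passing. There MT-TL1 (0.48), MTRNR2L12 (0.13), MT-TV (0.15), CYP4F3 (adjusted p = 0.914), MEIS1 (0.73) and SPRY4 (-1.45) lost the call, CDK6 (0.62) gained it and WDR43 (-0.56), ODC1 (-0.51), IGKJ1 (2.43), SLC15A2 (1.24), STRA6 (-3.31), PRG3 (-1.50), LYZ (0.92), MEF2C (-0.97) and MYC (-0.33) moved. ELN (adjusted p = 0.0057) and GABRA3 (adjusted p = 0.000145) had a group at 0 counts without DMSO replicate 1. CYP4F3 (adjusted p = 0.119) lost the call without selumetinib replicate 2. LYZ (0.33) moved without VTP-50469 replicate 1. ELN (-4.41) moved without VTP-50469 replicate 2. PBX3 (0.36) lost the call without VTP-50469 replicate 3. MEIS1 (0.61 to 0.67) lost the call without combination replicate 1, or VTP-50469 3.

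Between the lines, the day 6 combination effect differed in antigen presentation and stress genes. The effect on HLA-DRA (-6.96) was lower in NOMO1. The lipoprotein receptor gene VLDLR differed by 3.64 ± 0.23 (NOMO1 minus OCI-AML3, adjusted p = 5.31e-17, edgeR), the chaperone gene HSPA5 by 1.47 ± 0.13. Here 7 of 13 MHC class II genes were lower (median -2.15, adjusted p = 4.11e-06), and 19 of 20 stress genes were higher (median 2.62, adjusted p = 7.8e-23). Monocyte genes CD14 (9.60) and CYBB (3.28) were higher in NOMO1, and 16 of 25 monocyte genes were higher and 4 lower (17 up and 4 down adjusted over the list alone, median 1.33, adjusted p = 1.73e-07). The test called 3477 genes higher and 3054 lower. The largest upward were PTGIS (0 to 0.174 and 11 to 0.0182 CPM), DHRS3 (3.38 to 10.9 and 3.99 to 0 CPM), CHST15 (1.64 to 27.6 and 0.465 to 0 CPM), ABCG1 (0.655 to 14.4 and 0.317 to 0 CPM) and SYTL1 (80.7 to 121 and 3.87 to 0 CPM), and downward MEIS1 (28 to 0 and 40.2 to 26.3 CPM), IFI44 (0.158 to 0 and 0.199 to 13.4 CPM), SNORD3A (-9.0), ACOX2 (7.43 to 0.9 and 0 to 0.345 CPM) and VAT1L (10.2 to 0.0515 and 36.6 to 84.2 CPM), in CPM as DMSO to combination in NOMO1 and then OCI-AML3. Of the followed genes DUSP6 (2.19), MCL1 (0.41) and KMT2A (1.49) differed upward and PBX3 (-1.76), HOXA9 (-2.36), MEF2C (-4.35), FLT3 (-1.24), CDK6 (-1.07), SPRY4 (-2.23), ETV5 (-1.45), ITGAM (-4.21), LYZ (-1.79), MYC (-1.35) and NRAS (-0.34) downward. Not passing were PHLDA1, BCL2 and MEN1 (-0.35 to 0.67, adjusted p 0.114 to 0.353). In both lines 1804 genes rose (961 expected) and 2352 fell (1230 expected). PTGIS (adjusted p = 1) lost the call without NOMO1 combination replicate 2. IFI44 (adjusted p = 0.103) lost the call without NOMO1 DMSO replicate 1. ACOX2 (adjusted p = 1) lost the call without OCI-AML3 combination replicate 3. NRAS (-0.28 to -0.25) lost the call without NOMO1 DMSO replicate 2, or OCI-AML3 DMSO 3.

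**Figure D3:**
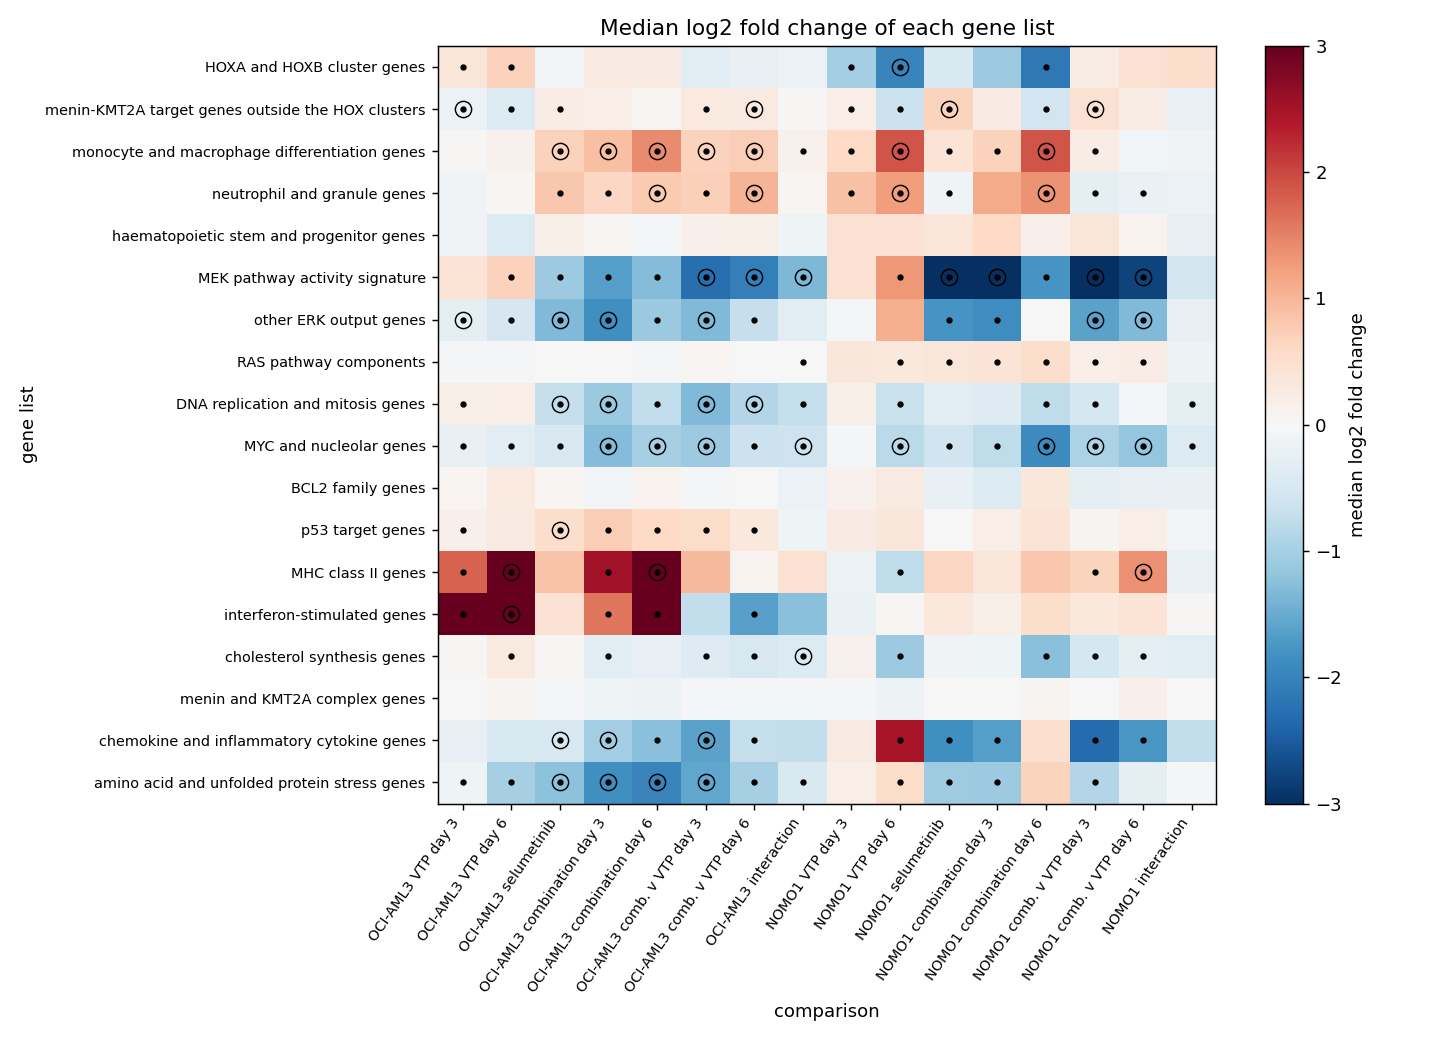
Median log2 fold change of the genes of each of the 18 lists (rows) in the 16 comparisons within 1 line (columns), as colour from -3 to 3, with a dot where the camera test passed with the preset correlation and a ring where it passed with the estimated one. In the VTP-50469 day 6 column of OCI-AML3 the interferon list has a median of 6.86.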

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

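The days in culture test, DMSO day 6 list tests and split number were chosen after seeing results.

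For VTP-50469 at day 6 the line difference test, NOMO1 minus OCI-AML3, called 6242 genes. Of the genes named, those with a higher log2 effect in NOMO1 were CLEC10A (10.62), C5AR1 (7.99), CD36 (5.90), CD14 (6.53), CYBB (3.95), DUSP6 (1.16), MCL1 (0.70), CEBPB (3.67), SLC7A11 (4.65) and KMT2A (0.80), and those with a lower one IFIT1 (-10.84), HOXA9 (-2.56), HOXA10 (-2.52), MEIS1 (-6.33), CDK6 (-1.74), HLA-DRA (-7.30), CIITA (-4.14), MX1 (-6.42), HMGCS1 (-3.0), PBX3 (-1.78), MEF2C (-3.04), FLT3 (-0.78), ITGAM (-2.62), LYZ (-0.42), MYC (-0.33), NRAS (-0.48) and MEN1 (-0.32). S100B (0.000676), PLA2G7 (0.00553), PPM1E (7.34e-06), LHFPL1 (0.00014), CLEC2B (1.06e-09), TLR3 (0.000727) and EPCAM (2.9e-05) had a group near 0 counts and are given by adjusted p. Lists that differed, by adjusted p (camera), were HOXA and HOXB genes (0.0015, alternatives 0.00173 to 0.0616 with an estimated correlation), monocyte genes (6.39e-19), MHC class II genes (7.27e-10), interferon-stimulated genes (8.83e-21) and cholesterol genes (1.87e-20).

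For selumetinib the line difference test called 6301 genes. Of the genes named, those with a higher log2 effect in NOMO1 were MYC (0.57), MCL1 (0.45), PBX3 (0.53), FLT3 (0.74), CDK6 (0.61), BCL2 (0.52) and NRAS (0.28), and those with a lower one LYZ (-0.92), S100A8 (-3.56), ETV5 (-4.70), DUSP4 (-3.81), CCND1 (-1.79), DUSP6 (-2.26), SPRY4 (-1.26) and ITGAM (-1.84). PRRG1 (1.87e-06), ALDH7A1 (7.63e-05), RASL10B (0.00338), KRT86 (0.00393), GIMAP6 (0.00456), APP (0.00473), GNG11 (0.000113), EPCAM (0.0052) and GHR (0.0408) had a group near 0 counts and are given by adjusted p. Lists that differed, by adjusted p (camera), were neutrophil genes (0.0015, alternatives 0.00187 to 0.527 with DMSO day 6) and MEK signature genes (3.58e-05, alternatives 5.98e-16 to 0.0525 with an estimated correlation). With DMSO day 6 as control 1797 genes were called, MCL1 (-0.09), FLT3 (-0.43), BCL2 (-0.48) and ALDH7A1 (-0.18) turned, and PBX3, CDK6, MYC, NRAS, PRRG1, RASL10B, GIMAP6, GNG11 and GHR lost the call.

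For the combination at day 6 the line difference test called 6531 genes. Of the genes named, those with a higher log2 effect in NOMO1 were CD14 (9.60), CYBB (3.28), DUSP6 (2.19), MCL1 (0.41), KMT2A (1.49), VLDLR (3.64) and HSPA5 (1.47), and those with a lower one SNORD3A (-9.0), HOXA9 (-2.36), MEF2C (-4.35), LYZ (-1.79), SPRY4 (-2.23), MYC (-1.35), HLA-DRA (-6.96), PBX3 (-1.76), FLT3 (-1.24), CDK6 (-1.07), ETV5 (-1.45), ITGAM (-4.21) and NRAS (-0.34). PTGIS (7.53e-06), DHRS3 (2.38e-09), CHST15 (2.01e-08), ABCG1 (9.18e-08), SYTL1 (2.81e-05), MEIS1 (2.71e-22), IFI44 (0.00575), ACOX2 (0.000734) and VAT1L (7.35e-16) had a group near 0 counts and are given by adjusted p. Lists that differed, by adjusted p (camera), were monocyte genes (1.73e-07), MHC class II genes (4.11e-06) and stress genes (7.8e-23).

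Libraries were also regrouped and refitted with only the compared groups. The 10 splits of 3 against 3 are too few for a share under 0.05; in OCI-AML3 the real splits called 1459 (VTP-50469 day 3), 7058 (VTP-50469 day 6), 6125 (selumetinib), 8087 (combination day 3), 6862 (combination day 6), 5924 (combination against VTP-50469 day 3) and 5379 (day 6), in NOMO1 6287 (VTP-50469 day 3), 8926 (VTP-50469 day 6), 8424 (selumetinib), 9179 (combination day 3), 9494 (combination day 6), 4835 (combination against VTP-50469 day 3) and 5616 (day 6), and the highest other split called 0 in each. For the interactions and line differences 60 splits were drawn, a number set for run time after smaller draws had been seen. Chance was not excluded for the OCI-AML3 interaction, where 3 splits, the real one included, gave at least its 1295 genes (highest other 2259). That of NOMO1 gave 5483 (1 split, highest other 2725). The line differences gave 7511, 6989 and 6301 genes for VTP-50469, selumetinib and the combination. In each, 1 other split, swapping all 6 OCI-AML3 labels, gave more (8265, 8335 and 9005). Splits also break up drug effects, so chance was excluded for none of these.

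The NOMO1 DMSO day 3 libraries stand apart from those of DMSO day 6. A few genes taking most counts cannot be judged, since TMM scaling already limits their weight. Without the 50 most abundant genes (13 mitochondrial, 34.7% of counts), 8266 of the 8447 genes called kept call and direction (8384 called). RNA of OCI-AML3 cells is argued against by a median of 0% of the OCI-AML3 level over 5 genes nearly silent in other NOMO1 groups (4 counts, upper 95% limit 0.033% pooled), and days in culture by the 71.3% of called genes that lay nearer to DMSO day 6 in the combination at day 3 (76.2% with VTP-50469). Gene length or GC bias cannot be told apart from a true change, since a fit on both explained 29.1% of the variance, over the 10% set beforehand as the bound against it and under the 50% set for it. A technical or culture state of these 3 libraries may be the cause, a hypothesis for which the labels give no batch.

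OCI-AML3 VTP-50469 day 3 replicate 2 lies towards day 6. RNA of NOMO1 cells is argued against by a median of 0% of the NOMO1 level over 30 genes nearly silent in other OCI-AML3 groups (2 counts, upper 95% limit 0.006%). Mixing with a day 6 library cannot be told apart from a faster response: rising genes sat at 0.45 and falling ones at 0.66 of the way, a difference of 0.21 (bootstrap 95% interval over genes 0.16 to 0.26) that spans the 0.2 set beforehand as the bound against mixing. No biological explanation was tested.

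For genes of 20 to 100 reads, replicates of the OCI-AML3 combination at day 6 scatter more than those of other OCI-AML3 groups. Lower total counts are argued against, since the ratio of the scatter was 3.4 with all libraries thinned to the lowest total. Unthinned, the ratio (9.13 against 3.04) reached the 3 set beforehand as the bound for few RNA molecules sequenced many times. Pairs ran 2.85 to 3.06, so that cannot be told apart from a true spread. No biological explanation was tested.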

How the results depend on the processing

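Chosen only after results had been seen were the tests with mitochondrial genes removed, with DMSO day 6 as control of VTP-50469 day 3 and combination day 3, for shared calls too, and all list tests with DMSO day 6 or without a VTP-50469 day 3 library. The counts of all 19 comparisons stayed within 1.5 times under DESeq2, relative log expression factors, library totals, no filter, the 1 CPM filter, only the compared groups and removal of mitochondrial genes. DMSO day 6 as control, run for 9 comparisons, moved 4. In NOMO1 VTP-50469 day 3 went from 8680 to 4499 genes, selumetinib from 8957 to 5328 and the interaction from 6134 to 2298, and the selumetinib line difference went from 6301 to 1797. Of calls shared by VTP-50469 day 3 and day 6 it moved those higher and then lower, from 1013 to 123 in NOMO1 and 1 to 2 in OCI-AML3, and the reverse in NOMO1 (542 to 275). Leaving out 1 library moved 2 of the 19. OCI-AML3 VTP-50469 day 3 (1788) ran from 964 without VTP-50469 replicate 2 to 1867 without VTP-50469 replicate 3, with 1139 and 1186 without DMSO replicate 1 and 3. The OCI-AML3 interaction (1465) ran from 970 without selumetinib replicate 1 to 1766 without VTP-50469 replicate 2.

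The replicate number as a block gave 1728 genes for OCI-AML3 VTP-50469 day 3, and all 19 counts stayed within 1.5 times, though the numbers do not pair libraries.

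Scaling by library totals moved the median of all genes by 0.131 in OCI-AML3 combination day 3, in NOMO1 by 0.325 (VTP-50469 day 3), 0.374 (selumetinib), 0.305 and -0.109 (combination day 3 and day 6) and -0.395 (interaction), and by -0.161, 0.258 and -0.156 in the line differences for VTP-50469, selumetinib and the combination. The share of calls that were higher went in OCI-AML3 from 59.5% to 71.1% (VTP-50469 day 3), 42.8% to 53.3% (selumetinib) and 46.4% to 57.9% (combination day 3). In NOMO1 it went from 56.7% to 78.4%, 53.4% to 76.2% and 53.1% to 69.6% in the same order and from 41.4% to 13.9% in the interaction, and in the line differences from 49.6% to 36.6%, 59.6% to 77.5% and 53.2% to 40%.

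Of the 689 gene results named, 679 of 687 kept direction and call under DESeq2, 684 under relative log expression factors, 648 under library totals, 660 with no filter, 684 of 687 with the 1 CPM filter, 650 of 684 with only the compared groups, 683 of 687 without mitochondrial genes and 265 of 312 with DMSO day 6. With DMSO day 6 these turned, with the cause not tested. In NOMO1 VTP-50469 day 3 they were MCM2 (-0.24), TOP2A (-0.41), MCL1 (-0.051), CYP51A1 (-0.53), SQLE (-0.62), FLT3 (-0.90), ITGAM (-0.17), MYC (-0.22) and BCL2 (-0.87), with selumetinib MEF2C (-0.21), ITGAM (-0.60) and BCL2 (-0.56), and in combination day 3 CDK6 (-0.40), ITGAM (-0.12) and MCL1 (-0.38). In the NOMO1 interaction BCL2 (0.11), FLT3 (0.73), ITGAM (0.65) and MCL1 (0.16) turned, in that of OCI-AML3 KIF13A (-0.64), and in the selumetinib line difference ALDH7A1 (-0.18), MCL1 (-0.09), FLT3 (-0.43) and BCL2 (-0.48). Library totals turned NRAS (0.27) and MEN1 (0.31) in NOMO1 VTP-50469 day 3, MYC (0.21) and MCL1 (0.37) with selumetinib and CDK6 (-0.38) in the interaction, by a shift of all genes. Leave-one-out fits gave the same call in 4943 of 5130.

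Of 81 list tests described, 56 kept their call with an estimated correlation, 80 under library totals, all 81 under the block, 24 of 31 with DMSO day 6 and 16 of 18 without a VTP-50469 day 3 library. With DMSO day 6 the replication genes turned upward in the NOMO1 interaction (adjusted p = 0.0457, alternatives 2.08e-05 to 0.591), and in NOMO1 VTP-50469 day 3 they turned downward (0.00696, alternatives 0.000598 to 0.684), as did the cholesterol genes (3.27e-11, alternatives 3.27e-11 to 0.882). Without OCI-AML3 VTP-50469 day 3 replicate 2 the interferon genes turned upward in the combination against VTP-50469 at day 3 (adjusted p = 0.00237, alternatives 0.00237 to 0.982).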
